A study of Mus musculus with 5 samples.

How the data were processed

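RNA sequencing of striatal homogenates from adult mice was analysed in 5 libraries: 3 from wild-type littermates (WT replicates 1, 2 and 3) and 2 from the Adcy5 R419W knock-in line (KI replicates 1 and 3). Genotype and replicate number were taken from the labels. The libraries were made with an Illumina stranded mRNA ligation kit, per the labels' protocols. No label ties each library to a separate animal, so p-values measure the spread between these libraries, which may be in part technical.

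The deposited values are raw counts of read pairs per gene feature, made with featureCounts 2.0.1, per the file headers. The recorded options counted pairs as fragments and assigned a fragment to each feature it overlapped. Multi-mapped reads were left out and strand was ignored although the kit marks strand, per the same headers, so overlapping and antisense genes cannot be told apart. The annotation was Ensembl release 103 of GRCm39, per the file headers. The aligner and the genome build of the alignment are not given in the sources used here. Total counts ranged from 6595105 to 7910584 per library, and a count of 0 allows a level of up to 0.379 to 0.455 CPM (3 counts of the total, covering counting error only).

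The positions of the counted reads did not match the annotation used for counting. The files' features were laid over the exons of GENCODE M21, an annotation of GRCm38, by their numeric positions alone with bedtools 2.31.1, and no coordinate was converted. Of 53700 features, 33901 (63.13%) had no GRCm38 exon at their positions, and those held 1.057% of the counts. Among features labelled protein coding, the 9117 without a GRCm38 exon had a median summed count of 0, against 292.0 for the 12812 with one. Protein-coding genes that lie at the same position in both annotations (563 genes) had a median of 120.6 counts per library, against 3.2 for the 20047 shifted by over 20000 bases. For 1016 GRCm38 genes with 2 separate features, the levels of both correlated across genes (Spearman rho 0.604, against at most 0.114 in 1000 shuffled pairings), although genes are not independent replicates. These values are what reads aligned to GRCm38 and counted at GRCm39 coordinates would give, so the gene label that the files attach to a feature was not used to name it. The 37 mitochondrial features and the 53 features on unplaced scaffolds also had 0 counts, which a difference in positions does not account for and whose cause was not tested.

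Each feature was instead named by the GRCm38 gene whose exons lie at its positions: the gene alone there or, where several were, the only protein-coding one. This choice was made after the data were seen. It named 16422 features, which cover 12586 genes (8669 of the 22028 protein-coding genes of GENCODE M21) and hold 57.63% of the counts. A further 3377 features lie over several genes that could not be separated and hold 41.31% of the counts. A named feature usually covers only part of a gene's exons, so its level is that of the covered part. For gene lists, each gene was represented by the feature with the largest overlap. Alternatives were lists built from the files' own labels and lists limited to features over 1 gene of any kind.

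The main comparison was KI against WT. Features were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 29.8%. CPM values use TMM-scaled library sizes, except the medians that compare gene lists by label and by position, which use total counts. A total of 37 gene lists was fixed before the data were examined and tested with camera of limma 3.58.1 (preset correlation 0.01) where at least 3 members were tested, which held for 29 lists. Lists of imprinted genes and of hypothalamic and ventral forebrain genes were written after the first results were seen. Features within 20 Mb of Adcy5 were compared with all others by a two-sided Fisher's exact test.

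The genes named in the text followed a rule set before the data were examined. It takes Adcy5 and then protein-coding genes with an adjusted p under 0.05, a mean CPM of at least 1 and both KI libraries beyond all 3 WT libraries: up to 12 per direction by fold change, filled up to 6 by the smallest p and then said to be below the threshold. From each list described it takes up to 4 members past the threshold or else the 2 with the smallest p. It also takes Drd1, Drd2, Adora2a, Penk, Pdyn, Tac1, Ppp1r1b, Gnal and Pde10a, and a further item of the rule is not reported here. Genes named outside the rule, among them Kcna5, Rgs6, Ttr, Prlr, Prkcd, Slc17a6 and the imprinted genes below the threshold, were chosen after their values were seen.

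The test was run on simulated counts for the KI and WT libraries over 12881 features, with 50 features changed at each of 4 folds. The changed features were drawn from those with a mean of at least 10 CPM. It recovered 10 of 50 at 1.5-fold, 32 at 2-fold, 43 at 3-fold and 48 at 6-fold, and 21 of its 154 calls were false, a larger share than the nominal 5%. In 40 simulated lists of 10 members, the 1 shifted list had a camera adjusted p of 0.00117 and no other was called. Each gene was simulated independently, so these runs do not show how the list test behaves where genes vary together. Alternatives were DESeq2 size factors, unscaled library totals, no low-count filter, a stricter filter, the DESeq2 1.42.0 Wald test, limma voom, the replicate number as a block, each library left out in turn, sex chromosomes left out, a false discovery rate of 0.10, glmTreat against a 1.2-fold change, camera with an estimated correlation, fry and a window of 5 Mb. The level of the cortical marker Slc17a7 was added as a covariate after the data were seen. A term for sex was not fitted, since the 4 Y-linked features summed to 0, 10 and 1 counts in the WT libraries and 2 and 0 in the KI libraries. Figures were drawn with matplotlib 3.10.9.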

Results

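The data are gene counts from striatal homogenates of adult mice that carry the Adcy5 R419W allele (KI, n = 2 libraries) and of wild-type littermates (WT, n = 3). Adcy5 encodes the main adenylyl cyclase of the striatum, the enzyme that makes cAMP downstream of dopamine and adenosine receptors, and the series concerns striatal cAMP in hyperkinetic movement disorders. The comparison asks which transcripts differ in the striatum when the allele is present. Total counts were 7786173, 7620283 and 6595105 in WT replicates 1 to 3 and 7282807 and 7910584 in KI replicates 1 and 3. Correlations of log2 CPM between libraries lay between 0.9333 and 0.9484, and no pair of libraries matched within sampling noise (chi-square per degree of freedom 6.51 to 20.3). WT replicates 2 and 3 had the highest correlation. WT replicate 1 correlated at 0.9441 with KI replicate 1, against 0.9367 and 0.939 with WT replicates 2 and 3.

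The gene labels in the files could not be taken at face value. By where the counts fall, the reads lie at GRCm38 positions, whereas the features they were counted on lie at GRCm39 positions. Ckb, a brain creatine kinase, is read by the feature labelled Gm36635 on chromosome 12 (8481 CPM on average), and the feature labelled Kmt2d on chromosome 15 lies over Arf3 (5147 CPM). Spiny projection neuron markers had a median of 2.81 CPM by file label (22 features) and 322.857 CPM by position (11 features). Ribosomal protein genes had 0.31 CPM (89 features) and 469.68 CPM (13 features). By position only members with a feature over their GRCm38 exons count, so a higher median there does not check the names. Genes are therefore named below by the GRCm38 gene at the feature's positions. The file's label often differs from that name and is given only for some of the genes.

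**Figure D1:**
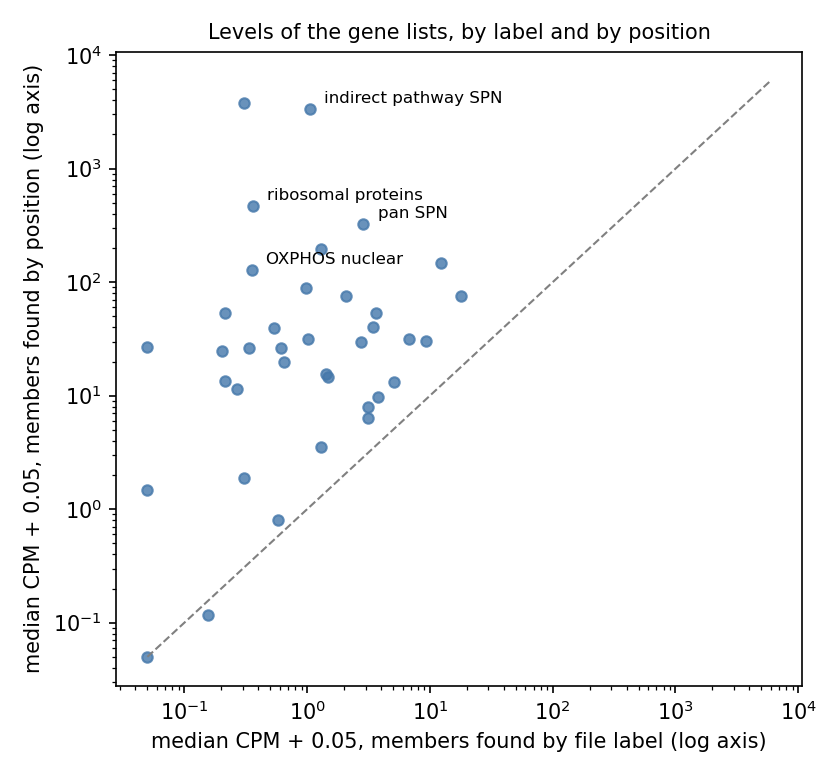
Median CPM over all libraries of each of the 37 gene lists, with members found by the files' own labels (x axis) or by GRCm38 position (y axis), both on log axes with 0.05 CPM added; each point is a list and the dashed line marks equal values. By position 35 of the 37 lists had the higher median. Members without a feature over their GRCm38 exons drop out by position, which by itself favours a higher median.

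Adcy5 itself could not be measured. It lies on chromosome 16 from 35154877 to 35305738 in GRCm38, and 0 of the features cover its exons. The feature labelled Adcy5 spans 34975247 to 35126108, a shift of -179630 bases from the gene's GRCm38 position, and lies over exons of Mylk, a myosin light chain kinase. It held 18, 31 and 28 counts in the WT libraries and 36 and 43 in the KI libraries. These values carry no information on the knocked-in gene or on the genotype labels.

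Of the 4 named genes higher in KI striatum past the threshold, Peg10, Usp29 and Peg3 are imprinted. Peg10, an imprinted gene derived from a retrotransposon, was 5.54-fold higher, at 959.0 ± 22.1 CPM in KI (SD, n = 2) against 173.2 ± 32.2 in WT (SD, n = 3). Usp29 was 2.09-fold higher and its imprinted neighbour Peg3, a zinc finger gene, 1.59-fold higher. Wfs1, which encodes the endoplasmic reticulum protein wolframin, was 2.02-fold higher. Lower in KI were 3 potassium channel genes (Kcns2, Kcnh3 and Kcnj4), the calcium-binding protein gene Necab1, and Abi3bp, Gpx6 and Sbsn.

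In total 14 of 13665 tested features changed at an edgeR quasi-likelihood adjusted p under 0.05, 6 higher and 8 lower in KI, and 874 had an unadjusted p under 0.05. All 14 had both KI libraries beyond all 3 WT libraries. Over all features, 3062 (22.4%) were separated in this way, where chance gives 20%. With unscaled library totals the split was 9 higher and 7 lower. Among the higher genes, Peg10 had a log2 fold change of 2.47 (SE 0.14, adjusted p = 1.433e-06) on chromosome 6 from 4747306 to 4760517, a position shared by both builds. Usp29 (log2 fold change 1.07, SE 0.12, adjusted p = 0.002089) lies on chromosome 7 from 6730578 to 6967219 and Peg3 (0.67, SE 0.09, adjusted p = 0.006394) from 6703892 to 6730431. Their features sit 2999 bases higher than the GRCm38 genes. That of Usp29 also covers exons of Gm44863 and Zim3. The feature labelled Zim3 overlaps Usp29 and gave 1.03, so it counts part of the same reads. Wfs1, on chromosome 5 from 36966104 to 36989205, was read by the feature labelled Man2b2 over 465 exon bases, with a log2 fold change of 1.01 (SE 0.14, adjusted p = 0.01081). The feature labelled Olfr1173 on chromosome 2, from 88103384 to 88110219, held 0, 1 and 0 counts in WT and 6540 and 2357 in KI, but no GRCm38 exon lies there and it was singled out after its values were seen. Below the threshold, Rgs10 (adjusted p = 0.05113) stood at 153.7 ± 0.54 CPM in KI and 92.1 ± 2.82 in WT, and Crem, a cAMP-responsive transcription factor gene, at 115.5 ± 24.0 and 59.1 ± 9.37 CPM (adjusted p = 0.06338). The feature over Crem also covers Gm6225.

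Among the lower genes, Abi3bp, a gene of the extracellular matrix, had the largest fold change at 8.59-fold (15.2 ± 3.63 CPM in WT against 1.76 ± 0.39 in KI, adjusted p = 0.01561). It was read over 234 exon bases by the feature labelled Tmem45a on chromosome 16. Gpx6, of the glutathione peroxidase family, was 6.02-fold lower (26.5 ± 2.71 against 4.37 ± 3.11 CPM, adjusted p = 0.03084, feature labelled Olfr263). Sbsn, the suprabasin gene, was 2.44-fold lower (75.6 ± 16.9 against 30.9 ± 0.23 CPM, adjusted p = 0.03282). Its feature is labelled Fxyd1 and also covers Tmem147os. Necab1 was 1.82-fold lower, at 546.4 ± 28.2 CPM in WT and 300.2 ± 17.7 in KI (adjusted p = 0.006394). The feature labelled Gm11837 covers the end of Necab1 and counts some of the same reads, with a log2 fold change of -1.03.

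Calls depended on single libraries and on the test. Without WT replicates 1, 2 and 3 in turn 161, 3 and 2 features changed, and without KI replicates 1 and 3 there were 30 and 6. The DESeq2 Wald test called 128 and limma voom 52, against 14 in the edgeR test. Peg10 passed in all 16 alternatives, with log2 fold changes from 2.27 to 2.58. Usp29 passed in 14 of 16, Wfs1, Kcns2 and Necab1 in 12, Peg3 in 11, Sbsn and Kcnj4 in 10 and Kcnh3 in 9, and of 15 alternatives that tested them Gpx6 passed in 11 and Abi3bp in 10. Rgs10 and Crem, below the threshold in the main test, passed in 8 and 7 of 16. The alternatives include the same edgeR test at a false discovery rate of 0.10, which each of these genes passes by its main adjusted p. None of these genes changed direction.

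**Figure D2:**
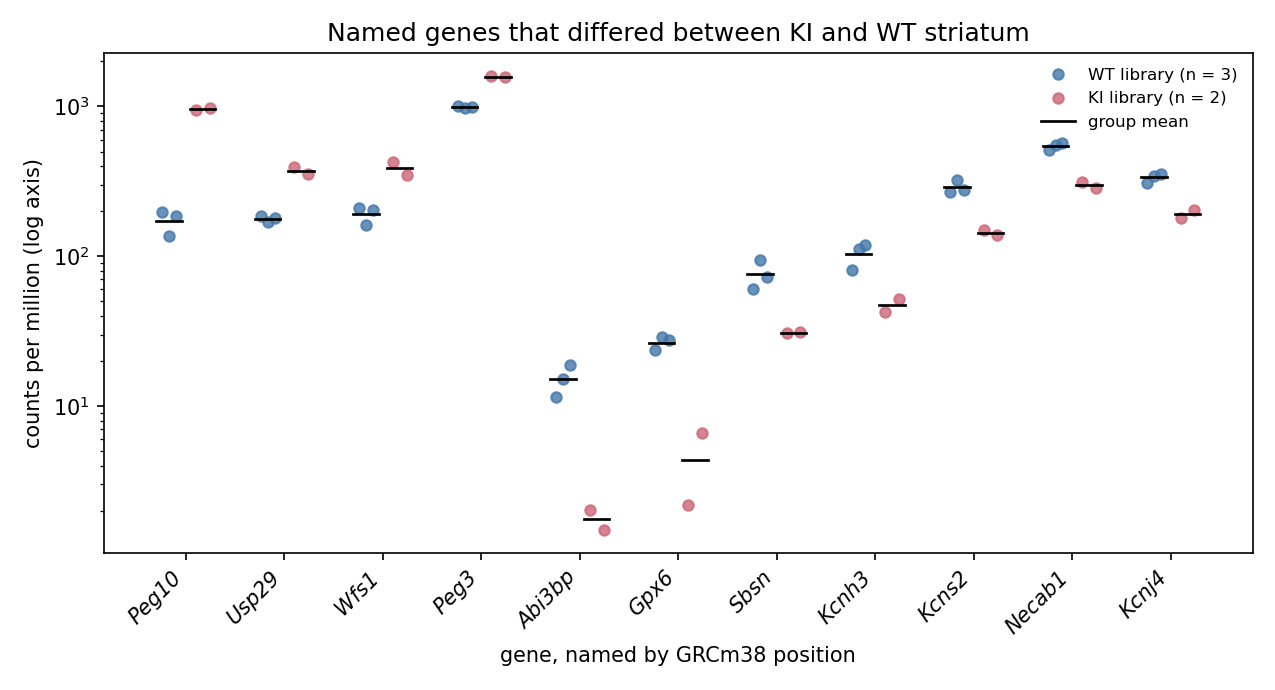
CPM on a log axis for the 11 named genes with an edgeR adjusted p under 0.05, by GRCm38 gene name; blue points are WT libraries (n = 3), red points KI libraries (n = 2) and black bars group means. For each gene both KI libraries lie beyond all 3 WT libraries, with Peg10 at 943.4 and 974.7 CPM in KI.

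Genes shared by spiny projection neurons, the output neurons of the striatum, were lower as a list in KI. Of 10 measured members 7 were lower, with a median log2 fold change of -0.28 (camera adjusted p = 0.0154). With an estimated correlation the unadjusted p was 0.206 and the adjusted p = 0.892. In the edgeR test no member passed over all genes and 1, Rgs9, passed when adjusted over the list alone; the DESeq2 Wald test called Rgs9 over all genes (adjusted p = 5.354e-06). Rgs9, a regulator of G protein signalling enriched in striatum, stood at 408.9 ± 103.3 CPM in WT and 200.1 ± 32.4 in KI (edgeR adjusted p = 0.06338). Pde10a, a striatal phosphodiesterase, stood at 793.6 ± 254.1 and 512.2 ± 69.2 CPM (adjusted p = 0.4763). The list's call was lost without WT replicate 2 (adjusted p = 0.233), without WT replicate 3 (0.221) and without KI replicate 1 (0.343).

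Levels of cortical neuron markers also differed between libraries. Slc17a7, the vesicular glutamate transporter of cortical projection neurons, stood at 73.6, 286.7 and 210.3 CPM in the WT libraries and 96.1 and 22.0 in the KI libraries. Neurod2 stood at 1.58, 32.1 and 30.0 CPM in WT and 6.64 and 1.73 in KI. The cortical list had a median log2 fold change of -0.61 over 5 members (camera adjusted p = 0.15), and in the edgeR test both genes passed only when adjusted over the list alone. The feature over Ttr, the transthyretin gene of the choroid plexus, held 16902 counts in KI replicate 3 and 207 to 415 in the other libraries. It also covers Gm16090, and Ttr was chosen after its values were seen.

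Of 16 measured members of the potassium channel list, 8 were higher and 8 lower in KI. Past the edgeR threshold 2 were lower and none was higher, and adjusted over the list alone Kcna5 was higher as well (log2 fold change 0.82, SE 0.25). Kcnj4, an inward rectifier, was 1.75-fold lower (336.3 ± 23.9 CPM in WT, 192.1 ± 18.0 in KI, edgeR adjusted p = 0.02619), and Kcnh3, a voltage-gated channel, 2.2-fold lower (104.0 ± 19.6 against 47.1 ± 6.61 CPM, adjusted p = 0.0392). Both were read over short exon stretches, 192 and 154 bases, by features labelled Dmc1 and Fmnl3. That over Kcnj4 also covers Gm49593. Kcns2, a modulatory subunit outside the list, was 2.02-fold lower over its exons (289.9 ± 30.8 against 143.8 ± 8.24 CPM, adjusted p = 0.006394). Slc17a7 was lower in the KI libraries than in WT replicates 2 and 3, as given above, and with its level as a covariate none of the 3 channel genes passed, at log2 fold changes of -0.81 for Kcnj4, -1.02 for Kcnh3 and -0.85 for Kcns2 (-0.81, -1.14 and -1.01 without it). The list as a whole had a median log2 fold change of -0.01 (camera adjusted p = 0.62).

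None of the 4 lists of cAMP pathway genes passed the test. The 12 measured genes of protein kinase A and other effectors included 6 higher and 6 lower in KI (camera adjusted p = 0.564), with Crem above and Prkar1a, a regulatory subunit, at 342.1 ± 47.8 CPM in KI and 288.8 ± 19.4 in WT. In the edgeR test 1 of them (Crem) was higher when adjusted over the list alone, and the DESeq2 Wald test (adjusted p = 0.000644) and limma voom (adjusted p = 0.0228) called Crem over all genes. Of 11 G protein subunits and partners 4 were higher (camera adjusted p = 0.859). Gnb4 stood at 34.8 ± 15.4 CPM in KI and 15.1 ± 3.97 in WT and Ric8b at a log2 fold change of -0.48 (SE 0.20), and in the edgeR test Gnb4 passed only when adjusted over the list alone. The 8 cAMP phosphodiesterases split into 4 higher and 4 lower (camera adjusted p = 0.8), led by Pde10a and by Pde3b at 1.06 (SE 0.56). Of 7 other adenylyl cyclases 4 were higher (camera adjusted p = 0.823), with Adcy4 at -1.87 (SE 1.22) and Adcy6 at -0.52 (SE 0.34).

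Regulators of G protein signalling split into 3 higher and 3 lower in KI (camera adjusted p = 0.629), and in the edgeR test Rgs10, Rgs9 and Rgs6 passed when adjusted over the list alone. The DESeq2 Wald test called all 3 over all genes. Among 7 measured neurotransmitter receptor genes 4 were lower, with a median log2 fold change of -0.54 (camera adjusted p = 0.13). Cnr1, the cannabinoid receptor gene, stood at 727.8, 1853 and 1771 CPM in WT and 596.9 and 729.6 in KI, so that WT replicate 1 lay within the KI range, and Grm8 at 36.8 ± 6.05 and 18.2 ± 2.78 CPM. In the edgeR test both passed only when adjusted over the list alone. Of 17 activity-dependent genes 8 were higher (camera adjusted p = 0.8), with Ier5 at -0.85 (SE 0.20) and Nr4a3 at 0.75 (SE 0.22). In the edgeR test both passed only when adjusted over the list alone, and the DESeq2 Wald test called Ier5 over all genes (adjusted p = 0.02124). Movement disorder genes were higher in 14 of 18 cases, with a median of 0.11 (camera adjusted p = 0.8), and the smallest p belonged to Frrs1l (-0.32, SE 0.10; DESeq2 adjusted p = 0.04685) and Pde10a.

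Glial, vascular and interneuron lists did not pass the test. Median log2 fold changes were -0.18 for oligodendrocyte, -0.09 for astrocyte, -0.23 for microglia, -0.10 for endothelial, 0.26 for oligodendrocyte precursor and 0.06 for GABAergic interneuron genes (camera adjusted p from 0.564 to 0.831). The myelin genes Cnp (824.4 CPM in KI, 1005 in WT) and Mag (251.9 and 307.6 CPM) had the smallest p of the oligodendrocyte list. In the other lists these were Slc1a3 and Aldh1l1 (-0.17 and -0.19), Aif1 and Trem2 (-0.35 and -0.62), Tek and Slc2a1 (-0.70 and 0.21), Vcan and Pdgfra (-1.13 and 0.37), and Th and Satb1 (0.46 and 0.16), none of which passed. Over all 29 tested lists, the camera adjusted p of those other than the spiny projection neuron list ranged from 0.13 to 0.888.

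**Figure D3:**
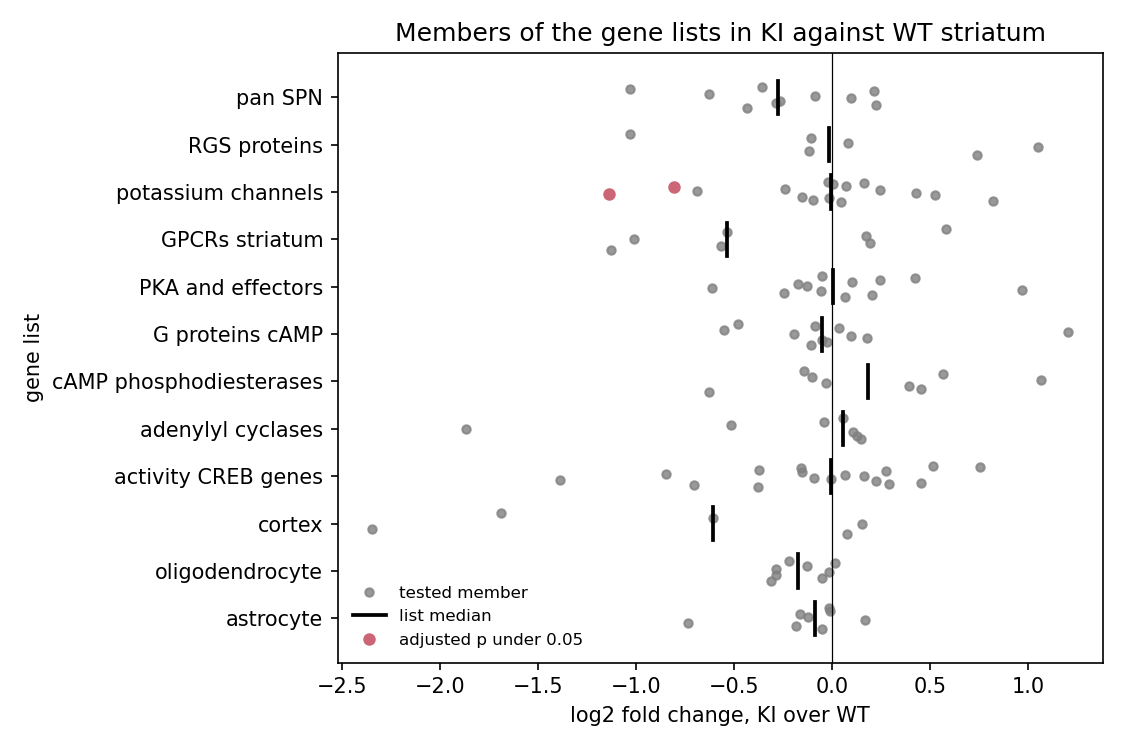
Log2 fold change of KI over WT (x axis) for each measured member of 12 of the gene lists (rows), as grey points, with members at an edgeR adjusted p under 0.05 in red and the list median as a black bar. Kcnj4 and Kcnh3 are the 2 red points, and the spiny projection neuron list has a median of -0.28.

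Of the striatal genes set out for reporting whatever their p, 0 features cover Drd1, Drd2, Adora2a or Pdyn, so their levels were not measurable. Penk, the enkephalin gene of the indirect pathway, stood at 7449 ± 778.9 CPM in WT and 5599 ± 429.0 in KI (log2 fold change -0.41, SE 0.09, edgeR adjusted p = 0.09917). Its feature also covers A830012C17Rik. A second feature over both genes, labelled A830012C17Rik, had a log2 fold change of -0.32 (SE 0.14, edgeR adjusted p = 0.7637). Tac1, the tachykinin gene of the direct pathway, stood at 915.3 ± 146.5 and 1008 ± 31.3 CPM (0.14, SE 0.12). Ppp1r1b, which encodes DARPP-32, was read together with Stard3 and Erbb2 by the feature labelled Ikzf3, with a log2 fold change of -0.57 (SE 0.10, adjusted p = 0.06338). The DESeq2 Wald test called Penk (adjusted p = 0.005221) and the feature over Ppp1r1b (adjusted p = 0.000122). Gnal shares its feature with Chmp1b (0.11, SE 0.14).

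Genes around Adcy5 on chromosome 16 were compared with all others. Of 211 tested features within 20 Mb, 0 had an edgeR adjusted p under 0.05, against 14 elsewhere (Fisher's exact test, two-sided, p = 1), too few calls to find a lower share in the window, while 16 had an unadjusted p under 0.05, the DESeq2 Wald test called 1 and limma voom 0. An unadjusted p under 0.01 was found for 2 features in the window (0.948%) and for 2.126% elsewhere (Fisher's exact test, two-sided, p = 0.333). Without WT replicate 2 the share in the window was 1.478% and above that elsewhere (Fisher's exact test, two-sided, p = 0.764). Abi3bp lies 21.3 Mb from Adcy5, just outside the window.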

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

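The Slc17a7 covariate and the naming of lists were chosen after the data were seen. Relative to 14 changed features (6 higher and 8 lower in KI), no low-count filter gave 183 (72 and 111), the replicate block 154 (60 and 94), the DESeq2 Wald test 128 (49 and 79), limma voom 52 (25 and 27) and a false discovery rate of 0.10 gave 67 (30 and 37). glmTreat against a 1.2-fold change gave 9 (4 lower), and the Slc17a7 level as a covariate gave 2 (2 higher, 0 lower). Leaving out 1 library gave 2 to 161 changed features, 2 to 51 higher and 0 to 110 lower, with the most calls without WT replicate 1. Without a KI library the remaining one is assumed to vary like the WT libraries. In the replicate block WT replicate 2 has no KI library of its number and adds nothing to the comparison. Little is then left to measure the spread between libraries. The 14 features were all shared with the calls made without a filter, with the block and without WT replicate 1, and 12 of them with the DESeq2 Wald test and limma voom. The cause was not tested, apart from the wider threshold and the fold bound, and 24598 features were tested without a filter and 4921 after DESeq2's own filtering. Of the values for named genes and the spiny projection neuron list under the alternatives, 155 stayed on the same side of the threshold, 15 came to pass it and 52 lost the call, and 0 changed direction. These counts include the wider threshold, where calls of the main test pass by definition.

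Where 1 gene list passed, no filter gave 4, the replicate block 2, an estimated correlation 0, fry 0, the Slc17a7 covariate 0 and members named by the files' labels 0. Leaving out 1 library gave 0 to 3 lists. The share of features near Adcy5 with a p under 0.01, 0.948%, was below that elsewhere, and its direction turned with the replicate block (4.265%) and without WT replicate 2 (range over left-out libraries 0.49% to 2.404%), with Fisher p of 0.429 and 0.764. The genotypes share replicate numbers 1 and 3, which makes 2 pairs and too few to treat the numbers as pairing. Deviations from the group means correlated at 0.111 for number 1 and 0.07 for number 3. With 2 KI libraries the KI deviations mirror each other, so these values are not separate checks and cannot decide on pairing. Scaling by library totals moved the median log2 fold change to 0.0467. The level of Adcy5 had no value under any setting because no feature covers its exons, and a term for sex was not run. Depth limits genes under about 0.4 CPM.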

Other observations

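The tests in this part were chosen after the first results were seen, but those of the chromosome 2 window and the other splits before their own values were known. Beyond Peg10, Peg3 and Usp29, further imprinted genes stood higher in KI striatum. All 7 genes expressed from the paternal allele were higher, leaving out Rtl1 and Kcnq1ot1, whose reads cannot be assigned to a strand. The feature over Rtl1 also covers Meg3 and Rian. Usp29 was kept, although its feature also covers Gm44863 and Zim3 and its reads cannot be assigned to Usp29 alone. The median log2 fold change of the 7 was 0.67, the value of Peg3. The 3 past the edgeR threshold are Peg10, Peg3 and Usp29, which prompted the list, so a test of the whole list is not independent of them. Zdbf2 stood at 51.2 CPM on average in KI and 27.9 in WT, and Rasgrf1 at 326.7 and 258.0. Sgce and Peg13 hardly differed, at log2 fold changes of 0.12 (SE 0.15) and 0.07 (SE 0.15). Of 11 genes expressed from the maternal allele 6 were higher (camera p = 0.00103, and 0.0903 with an estimated correlation), in a list also written after the first results were seen. Among them were Meg3 (log2 fold change 0.50, SE 0.11), Zim1 (1.65, SE 0.34) and, at low levels, the calcitonin receptor gene Calcr (16.9 and 12.6 CPM in KI, 0 to 4.73 in WT). Zdbf2, Rasgrf1, Sgce, Peg13, Meg3, Zim1 and Calcr did not pass in the edgeR test. The DESeq2 Wald test called Meg3 (adjusted p = 0.001812) and Zdbf2 (adjusted p = 0.0406).

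The rise of Peg10, Usp29 and Peg3 was set against a shared change of imprinted genes and against tissue brought in by dissection. The 17 imprinted genes left after removing those called were higher in 12 cases (camera p = 3.66e-06, and 0.032 with an estimated correlation). Without Rtl1 and Kcnq1ot1 10 of 15 were higher (camera p = 1.54e-05, and 0.0384 with an estimated correlation). Most of the other listed genes thus stood higher as well. The lists were written after the 3 genes were seen, so these tests are not independent of them and cannot settle a shared change. Several imprinted genes are abundant in hypothalamus and ventral forebrain, and 7 other genes of those regions had a mean log2 fold change of 0.397 (SE over genes 0.113), which came from KI replicate 1: 0.658 (SE 0.209) without KI replicate 3 and -0.081 (SE 0.197) without KI replicate 1. More ventral tissue may therefore contribute to the rise in KI replicate 1. The mean of -0.081 gave no sign of it in KI replicate 3, where none of the 7 genes lay above all WT libraries. Without KI replicate 1, however, 4 of the 7 were higher, and imprinted genes abundant in those regions were left out. Ventral tissue in KI replicate 3 is thus not excluded. Without KI replicate 1 the log2 fold changes were still 2.491 for Peg10, 0.98 for Usp29 and 0.654 for Peg3, and an effect of the allele stays open and untested.

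The genes lower in KI were set against differences in dissected tissue and in cell share. With the Slc17a7 level as a term, the median log2 fold change of the 7 named genes was -1.006 (-1.141 without it). All 7 lay over 2 standard errors below 0, and their calls ended as the median standard error grew from 0.188 to 0.286. The term cannot decide on less cortical tissue, since the genes were chosen for KI levels below all WT libraries. Slc17a7 was lower in WT replicate 1 than in KI replicate 1, so genes that followed it closely would not have been chosen. Without KI replicate 3, the library with the Ttr signal, the median was -1.291. A level below all WT libraries in KI replicate 1 was required of these genes, so the value cannot decide on choroid plexus tissue. Prlr, another choroid plexus marker chosen after its values were seen, stood at 26.4 and 51.4 CPM in KI and 4.95 to 14.8 in WT. For the spiny projection neuron list, a smaller share of these neurons was considered. The 30 glial and endothelial genes had a mean log2 fold change of -0.159 (SE over genes 0.06, although genes are not independent), so they were not higher as a set. A share lost to other neurons need not raise these genes, so the mean cannot decide on a smaller share. Less cortical tissue by itself would raise the share of striatal transcripts, whereas that list was lower. With the Slc17a7 term its median was -0.2 (camera adjusted p = 0.38), and WT replicate 1, low in Slc17a7, lay within the KI range for Cnr1 and Pde10a. Other differences in dissected tissue therefore cannot be told apart from an effect of the allele for that list.

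The feature labelled Olfr1173 held 8897 counts in KI and 1 in WT, a ratio of 12884 after division by the total counts of each group (95% exact interval 2312 to 508938, counting error only). The highest summed KI count of the 19 other features within 200 kb was 1. These features need not cover the GRCm38 exons of neighbouring genes, so run-over from such genes cannot be excluded. Of 147 tested features within 20 Mb, 4.08% had a p under 0.01 against 2.08% elsewhere (Fisher's exact test p = 0.133), so a stretch of another strain's sequence cannot be told apart from an inserted or rearranged transcript without the reads. The locus is on chromosome 2, not on chromosome 16 with Adcy5.

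Of the 10 splits of the 5 libraries into 3 and 2, 3 gave at least as many changed features as the genotype split, which is 1 of the 3. The genotype split gave 14, the split of both replicates numbered 1 from the others 43, and WT replicates 2 and 3 against the rest 31. The splits are too few for a share under 0.05. The split with 43 points to a structure of the samples other than genotype. Prkcd and Slc17a6, chosen after their values were seen from a list for septum, pallidum and thalamus, stood at 90.5 and 47.8 CPM in WT replicate 1 and at 47.6 and 32.9 in KI replicate 1, against 4.21 to 14.8 in the others. The first principal component (30.33% of the variance) placed WT replicate 1 at -63.39 and KI replicate 1 at -20.08 against 23.77 to 30.5 for the others.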
